A study of Arabidopsis thaliana with 24 samples.

How the data were processed

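Leaves of Arabidopsis thaliana were profiled on Affymetrix ATH1 arrays, with at least 15 seedlings pooled per sample per the labels' protocols, and plants kept under 10 h of light and 14 h of dark. The labels give 2 biological replicates for each of the 12 combinations of genotype and salt. The authors made the expression values with GCOS and RMA, per the submitters' processing notes; versions are not given in the sources used here. The deposited values are on a log2 scale, read from their range of 2.9 to 14.3, and were used as deposited. RMA subtracts background and normalizes arrays together, so a change shared by most probe sets between groups would be reduced in these values. Groups were taken from the sample titles and characteristics. The description texts of the CBF3 and M6PR samples name the other background, and the closing section gives the test of that conflict.

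Of 22810 probe sets, 64 controls were left out and 22746 tested. In the table of probe genes, 13513 of these had 1 gene, 503 several and 8730 none. Symbols were updated by gene ID from a RefSeq table of assembly TAIR10.1, which matched 13436 probe sets; no coordinates are given since the build behind the probes is not named. The transgenes' own probe sets (DREB1A for CBF3, SOS1) are not paired with a gene in that table and could not be picked out. The labels were therefore not checked by the targeted gene. Only 39 of 315 entries of the 23 gene lists written before the data were examined had a single-gene probe set. The CBF regulon had 4 of 16, flavonoid and anthocyanin 4 of 17, jasmonate response 3 of 18 and the abscisic acid list 1 of 23. Sodium and potassium transport had 0 of 18. Counts of list members below are of the measured ones.

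Groups were compared with limma 3.58.1 in R 4.3.3: 1 mean per group over all 24 arrays, 12 residual degrees of freedom, moderated statistics (prior degrees of freedom 3.11), two-sided, with Benjamini-Hochberg adjustment over probe sets within each comparison and a threshold of 0.05. There were 12 two-group comparisons (6 of a line against its matched wild type and 6 of salt within a genotype), 3 interactions of a line and its wild type, an average of salt over wild types and 3 differences between line effects. Errors of log2 fold changes are SE from that fit, so they pool the spread of all groups and not only of those compared. Detection calls were not used here, so a log2 change from a level near the lowest signals is a difference of signals, without a check that the lower one was above background. Gene lists with at least 3 measured genes (7: CBF regulon, flavonoid and anthocyanin, jasmonate response, mannose and ascorbate, antioxidant, photosynthesis, gibberellin) were tested with camera at a preset correlation of 0.01, two-sided, adjusted over lists within a comparison, and again with an estimated correlation. The list calls that held with an estimated correlation were those of the CBF regulon in CBF3 against Ws at both salt levels, salt in Ws and the CBF3 interaction. A further 32 gene families were written from the annotation before any test, and 24 with at least 5 genes were tested alike. Apart from the chloroplast-encoded genes, a family held the genes with a single-gene probe set whose symbol or synonym matched a pattern. Members without such a match were left out. Families for ribosomal proteins, photosystems, late embryogenesis abundant proteins, the cell cycle, cytochrome P450s, nitrate transport and defensins are not reported, because their patterns matched overlapping or unrelated genes, as was seen after the tests.

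The rule for named genes was fixed with those lists. The targeted gene came first, where it could be measured. Per two-group comparison these were the 8 largest rises and 8 largest falls among single-gene probe sets that passed and whose groups did not overlap, and up to 4 passing members of each list. For interactions and differences they were the 5 smallest p-values, or 3 where nothing passed. List members that did not pass show the rest of a list. The size of change is the root of the mean product of 2 independent differences. The mean products of both pairings of arrays are averaged before the root is taken. The root of a negative mean product is given a negative sign. Correlations of fold changes are across probe sets, which are not independent replicates, and were taken only between comparisons that share no array; some of these 17 pairs were added after the data were seen.

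The scripts were tested on simulated data with 200 of 22746 probe sets changed. For CBF3 against Ws without salt, 60% of changes of 1 log2 unit and 94% of changes of 2 were recovered. For salt in Colgl these were 64% and 96%. The simulated noise of a probe set had the same SD in all groups. In the real data the SD of the replicate difference ran from 0.17 in Colgl_0mM to 0.63 in SOS1_0mM. The recovery rates therefore check the scripts and do not give the power of the real comparisons. Alternatives were a filter on dim probe sets, a separate fit per background, a replicate block, quantile normalization, median centring, a trended and robust variance model, array weights, exclusion of cross-hybridizing probe sets and each array left out in turn. A pair of settings was chosen after seeing the data: a fit without the 2 arrays with a low dap spike-in, and a crossed pairing of replicates.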

Results

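Leaf RNA of Arabidopsis thaliana was measured on 24 Affymetrix ATH1 arrays, in 12 groups of 2 biological replicates. The groups were 3 transgenic lines and their wild types, each grown without NaCl and with 100 mM NaCl. The CBF3 line, in the Wassilewskija (Ws) background, overexpresses a transcription factor of the cold response. The M6PR line, in Columbia (Col), carries a celery gene for mannose-6-phosphate reductase, an enzyme of mannitol synthesis. The SOS1 line, in a glabrous Columbia (Colgl), overexpresses a sodium/proton antiporter of the plasma membrane. Salt was raised in steps of 50 mM from day 14, and plants were sampled on day 20 after sowing, 6 days after salt began. The comparisons ask how far each transgene changed the leaf transcriptome, with and without salt.

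Replicates differed to unlike degrees. The SD of the difference between the 2 arrays of a group, over probe sets, was 0.17 log2 units in Colgl_0mM and 0.63 in SOS1_0mM, the lowest and highest of the 12 groups. Array medians lay between 5.77 and 6.09 log2 units. A pair of arrays stood apart in their controls. The dap spike-in read 6.73 in Ws_100mM replicate 1 and 7.1 in Col_100mM replicate 1, against 9.5 to 11.3 in the other 22 arrays. The 25S rRNA probe set read 4.98 and 4.52 there, against 6.58 to 10.4. The 3' minus 5' signal of actin was 3.84 in both, against 2.15 to 3.15. The number of arrays, 2 per group, limits the precision of every value.

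**Figure D1:**
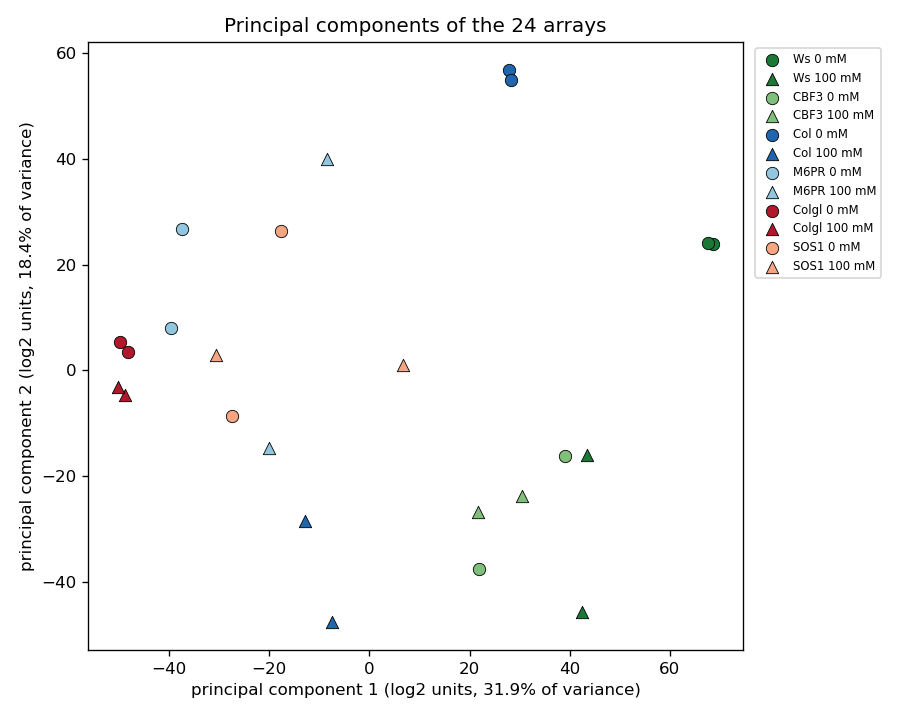
First (x axis, 31.9% of variance) and second (y axis, 18.4% of variance) principal components of the log2 values, one point per array, with colours for lines and shapes for salt. The Col_0mM arrays lie at 27.92 and 28.33 on the first component and the Colgl_0mM arrays at -49.85 and -48.16.

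Without salt, the 4 measured genes of the CBF regulon, the cold-induced targets of CBF factors, were all higher in CBF3 than in Ws. LTI30, a dehydrin, rose by 8.55 ± 0.44 log2 units (SE, n = 2 arrays per group, adjusted p = 1.9e-08), from 4.46 ± 0.08 to 13.01 ± 0.08 (SD, n = 2). The Ws level lay below the median signal of its arrays (5.97 and 5.95), and whether it was above background was not checked. COR15B and COR15A, which encode chloroplast proteins of the cold response, rose by 5.57 ± 0.39 and 3.27 ± 0.18, and the dehydrin gene COR47 by 4.41 ± 0.29. As a list the 4 genes passed (camera adjusted p = 5.7e-18, and adjusted p = 0.00078 with an estimated correlation), and all 4 passed when adjusted over the list alone. Other large rises were those of AT5G62360 (6.28), AT1G68500 (5.43), AT1G51090 (5.43), AT1G16850 (5.27), AT4G30650 (5.03) and AT2G33850 (5.02), with log2 fold changes in brackets. The largest falls were those of CSLA01 (-4.38), AT2G27420 (-4.13), AT1G20070 (-3.85), AT5G42760 (-3.47), AT3G14395 (-3.15), JMT (-3.05) and TBL26 (-3.02), with TRY among them, 8-fold lower (adjusted p = 3.8e-05). JMT methylates jasmonic acid, and TRY is a repressor of trichome formation. In the jasmonate list 1 of 3 measured members fell over all probe sets and 2 when adjusted over the list alone (camera adjusted p = 0.047, and adjusted p = 0.25 with an estimated correlation). PDF1.2, a defensin gene, had a log2 fold change of -3.18 ± 0.98 that did not pass over all probe sets. That SE pools the spread of all groups. The SD of PDF1.2 was 0.19 in Ws_0mM and 0.171 in CBF3_0mM, but 2.54 in M6PR_0mM. STZ, a zinc finger gene, rose by 2.59 ± 0.62 and the clock gene GI by 1.99 ± 0.49. STZ averaged 4.71 in Ws_0mM and 7.30 in CBF3_0mM, but 7.72 in Ws_100mM and 7.90 in CBF3_100mM. Fold changes of CBF3 against Ws correlated with those of salt in Col, which share no array, at r = 0.54. Between them 286 calls were shared upward and 452 downward, against 73.7 and 88.4 for independent lists, and 29 were opposite. How far the shared changes come from the transgene or from a state of Ws_0mM was not tested. In all, limma called 1545 of 22746 probe sets, 728 higher and 817 lower in CBF3, of which 921 changed at least 2-fold. The CBF3 count without salt was 463 (252 higher and 211 lower) without Ws_0mM replicate 1, 597 (333 higher and 264 lower) without Ws_0mM replicate 2 and 473 (301 higher and 172 lower) without CBF3_0mM replicate 1. Other settings gave 3780 with array weights.

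With salt, the CBF regulon genes were again higher in CBF3. LTI30 rose by 6.11 ± 0.44 log2 units (SE, n = 2 arrays per group, adjusted p = 1.2e-06), COR15B by 4.14 ± 0.39, COR47 by 2.26 ± 0.29 and COR15A by 1.66 ± 0.18. The 4 genes passed as a list (camera adjusted p = 3.3e-12, and adjusted p = 0.0043 with an estimated correlation). Further rises were those of AT5G62360 (5.69), AT1G51090 (4.99), AT1G68500 (4.52), AT2G16990 (4.23), AT2G24560 (3.80) and AT1G11210 (3.72), as log2 fold changes. XTH19, a xyloglucan-modifying enzyme of the cell wall, fell by 3.49 on the log2 scale, JMT by 2.40, TRY by 1.97 and the defence factor gene WRKY53 by 1.70. The largest falls also took in AT5G03350 (-3.15), AT2G34810 (-2.48), AT4G21650 (-2.47), AT5G51440 (-2.45), CSLA01 (-2.41) and AT1G62660 (-2.37). The jasmonate list had 1 of 3 measured members lower, 2 when adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.25 with an estimated correlation). CBF3 and Ws differed in 848 probe sets, 411 higher and 437 lower (530 higher and 326 lower with each array centred on its median), and the median fold change of all probe sets was 0.04 as deposited and 0.14 with centred arrays. Of the probe sets called at either salt level, 247 were higher and 157 lower at both, against 13.2 and 15.7 for independent lists, and fold changes at 0 and 100 mM correlated across probe sets with r = 0.5. The CBF3 count with salt was 312 (160 higher and 152 lower) without Ws_100mM replicate 1, 1367 (692 higher and 675 lower) without Ws_100mM replicate 2 and 278 (163 higher and 115 lower) without CBF3_100mM replicate 1. Other settings gave 318 without the 2 arrays with a low dap spike-in.

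**Figure D2:**
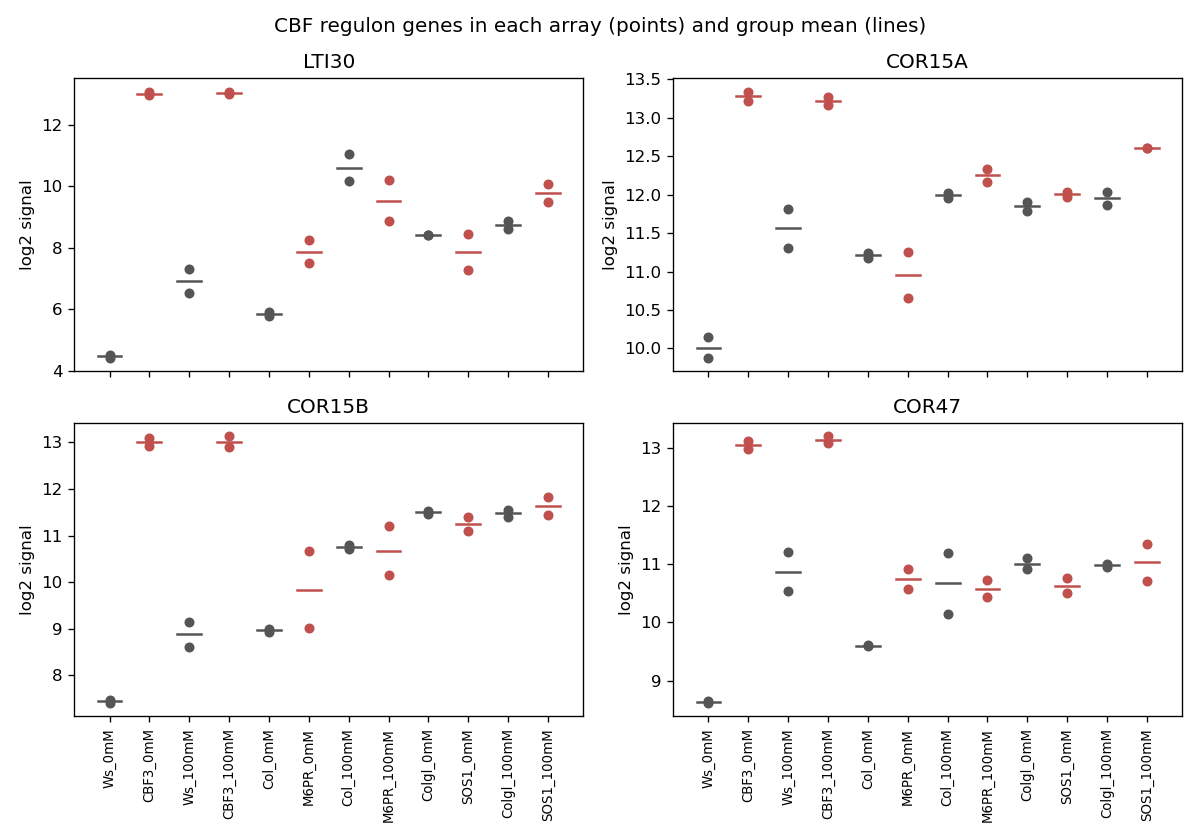
Log2 signal (y axis) of 4 CBF regulon genes in the 12 groups (x axis), with a point for each of the 2 arrays, a line at the group mean, wild types in grey and transgenic lines in red. LTI30 averaged 13.01 in CBF3_0mM and 4.46 in Ws_0mM.

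Without salt, the expansin-like gene EXLA1 was 6.88 ± 0.86 log2 units higher in M6PR than in Col (SE, n = 2 arrays per group, adjusted p = 0.00025), and EXO, a growth-related gene, 5.88 ± 0.97 higher. Anthocyanin genes were lower: UF3GT and AT4G14090, for glycosyltransferases, fell by 3.41 and 3.89 on the log2 scale, and the malonyltransferase gene AT5MAT fell by 2.91. Of the 4 measured members of the flavonoid and anthocyanin list, 3 fell over all probe sets and 4 when adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.1 with an estimated correlation). In the CBF regulon, LTI30 rose by 2.01 ± 0.44 and COR47 by 1.14 ± 0.29, 2 of 4 members (camera adjusted p = 0.019, and adjusted p = 0.36 with an estimated correlation). COR15A and COR15B had log2 fold changes of -0.25 and 0.87 that did not pass. The Col_0mM arrays stood apart from those of the other Columbia wild type, Colgl_0mM, in 3209 probe sets, against 8 for M6PR_0mM, in comparisons added after the data were seen. Those counts do not show which of the groups is the unusual one. In these groups UF3GT averaged 10.17 in Col_0mM, 6.76 in M6PR_0mM and 7.11 in Colgl_0mM, AT4G14090 averaged 10.04 in Col_0mM, 6.16 in M6PR_0mM and 6.69 in Colgl_0mM, LTI30 averaged 5.85 in Col_0mM, 7.86 in M6PR_0mM and 8.42 in Colgl_0mM, and COR47 averaged 9.60 in Col_0mM, 10.75 in M6PR_0mM and 11.01 in Colgl_0mM. The calmodulin-like gene CML38, from the list for handling or touch, rose by 4.17 ± 0.92, STZ by 3.32 ± 0.62 and CCS, a copper chaperone for superoxide dismutase, by 1.34 ± 0.22. TRY fell by 2.73. Other large rises were AT3G15630 (6.69), AT3G15450 (5.98), AT3G59350 (5.63), AT5G19120 (5.47), AT1G50040 (4.72) and AT2G25735 (4.62), and other large falls AT2G15020 (-4.27), AT1G60590 (-3.85), AT1G20070 (-3.78), AT2G27420 (-3.74), GH9C2 (-3.41) and AT2G44940 (-3.27). limma called 2346 probe sets, 1108 higher and 1238 lower in M6PR, 1428 of them at least 2-fold. The M6PR count without salt was 944 (528 higher and 416 lower) without Col_0mM replicate 1, 1015 without Col_0mM replicate 2, 1220 without M6PR_0mM replicate 1 and 1000 (550 higher and 450 lower) without M6PR_0mM replicate 2. Other settings gave 5332 with array weights.

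With salt, M6PR and Col differed in 120 probe sets, 39 higher and 81 lower in M6PR. GRX480, a glutaredoxin gene of the salicylate list, fell by 1.83 log2 units (SE 0.34, n = 2 arrays per group, adjusted p = 0.029), the calmodulin-like gene CML23 by 1.79 and the glycosyltransferase gene UGT76E12 fell by 2.60. Further falls were AT4G27654 (-3.24), AT3G01830 (-2.89), AT3G02840 (-2.20), AT2G22880 (-2.12) and AT1G43910 (-1.86), and the largest rises were AT4G16000 (1.78), AT1G78450 (1.72), AT3G23880 (1.59), AT1G78460 (1.41), AT3G15570 (1.41), AT1G67860 (1.38), AT5G37710 (1.25) and AT3G61210 (1.18). The 4 flavonoid and anthocyanin genes and the 4 CBF regulon genes did not pass; UF3GT was at -0.18 and LTI30 at -1.08. The split was 71 higher and 75 lower after quantile normalization and 74 higher and 45 lower with centred arrays, and the median fold change of all probe sets was 0.05 as deposited and 0.23 with centred arrays. Fold changes at 0 and 100 mM correlated with r = 0.01 across probe sets, while 11 calls were shared upward and 11 downward, against 1.9 and 4.41 for independent lists, and 3 were opposite. At an unadjusted p below 0.05 there were 5304 probe sets, against 4618 without salt. The M6PR count with salt was 27 without Col_100mM replicate 1, 449 without Col_100mM replicate 2, 10 without M6PR_100mM replicate 1 and 3720 without M6PR_100mM replicate 2. Other settings gave 58 without the dimmest 40% of probe sets, 49 with a separate fit per background, 37 with array weights and 42 without the 2 arrays with a low dap spike-in.

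Without salt, UF3GT was 2.23 ± 0.47 log2 units higher in SOS1 than in Colgl (SE, n = 2 arrays per group, adjusted p = 0.033). It was 1 of 4 flavonoid and anthocyanin genes to rise over all probe sets, and 3 did when adjusted over the list alone (camera adjusted p = 7e-05, and adjusted p = 0.15 with an estimated correlation). The chloroplast genes rpl16, rps4 and atpA rose by 2.64, 2.02 and 1.57, QQS, a gene known for its effect on starch, by 2.37 ± 0.23, and the ERF factor gene ORA47 by 2.25. Further rises were AT1G60590 (2.38) and AT3G23170 (1.87). The calmodulin-like gene CML42 fell by 2.34 on the log2 scale, and other falls were AT1G72060 (-3.01), AT3G23550 (-2.55), AT4G25390 (-2.49), AT1G26270 (-2.33), AT5G05300 (-2.28), AT3G16530 (-2.22) and AT4G28085 (-2.05). The Colgl_0mM arrays enter all these changes and differed from Col_0mM in 3209 probe sets. A state of Colgl_0mM was therefore not told apart from an effect of the line. limma called 281 probe sets, 81 higher and 200 lower in SOS1 (76 higher and 413 lower with centred arrays). The SOS1 count without salt was 16 without Colgl_0mM replicate 1, 28 without Colgl_0mM replicate 2, 44 (25 higher and 19 lower) without SOS1_0mM replicate 1 and 4439 without SOS1_0mM replicate 2. Other settings gave 51 (40 higher and 11 lower) with a separate fit per background, 489 with each array centred on its median and 8 with array weights.

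With salt, 3 of the 4 anthocyanin genes were higher in SOS1: UF3GT by 2.68 ± 0.47 log2 units (SE, n = 2 arrays per group), AT4G14090 by 2.46 ± 0.57 and AT5MAT by 2.35 ± 0.45. The list passed (camera adjusted p = 2.5e-05, and adjusted p = 0.12 with an estimated correlation), and 3 members passed when adjusted over the list alone. DFR, an earlier enzyme of the pathway, was at 1.08 ± 0.72 and did not pass. QQS rose by 2.18 ± 0.23, and other rises were AT1G13650 (3.18), AT1G04770 (2.99), AT1G60590 (2.85) and TBL26 (2.17). The largest falls were AT3G23550 (-3.90), AT1G72060 (-3.70), AT1G52200 (-3.53), AT2G39400 (-3.10), AT1G22890 (-2.96), AT4G25390 (-2.91), AT3G16530 (-2.86) and AT5G18470 (-2.58). SOS1 and Colgl differed in 713 probe sets, 327 higher and 386 lower. Their fold changes correlated across probe sets with those of salt in M6PR at r = 0.66, without a shared array. Of these calls 18 were shared upward and 56 downward, against 0.532 and 1.46 for independent lists, and 0 were opposite. With M6PR against Col without salt r was -0.66, with 425 calls opposite and 2 shared. Part of the change is therefore not particular to SOS1, and what links the comparisons was not tested. The subtracted groups lay near each other on the first principal component, Colgl_100mM at -48.85 and -50.19 and M6PR_0mM at -37.37 and -39.58. A state of the Colgl arrays was therefore not told apart from an effect of SOS1. Between salt levels, 43 calls were shared upward and 127 downward, against 1.16 and 3.39 for independent lists, and fold changes correlated with r = 0.73 across probe sets. The SOS1 count with salt was 88 without Colgl_100mM replicate 1, 115 without Colgl_100mM replicate 2, 1483 without SOS1_100mM replicate 1 and 183 without SOS1_100mM replicate 2. Other settings gave 246 (161 higher and 85 lower) with a separate fit per background and 1145 with array weights.

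**Figure D3:**
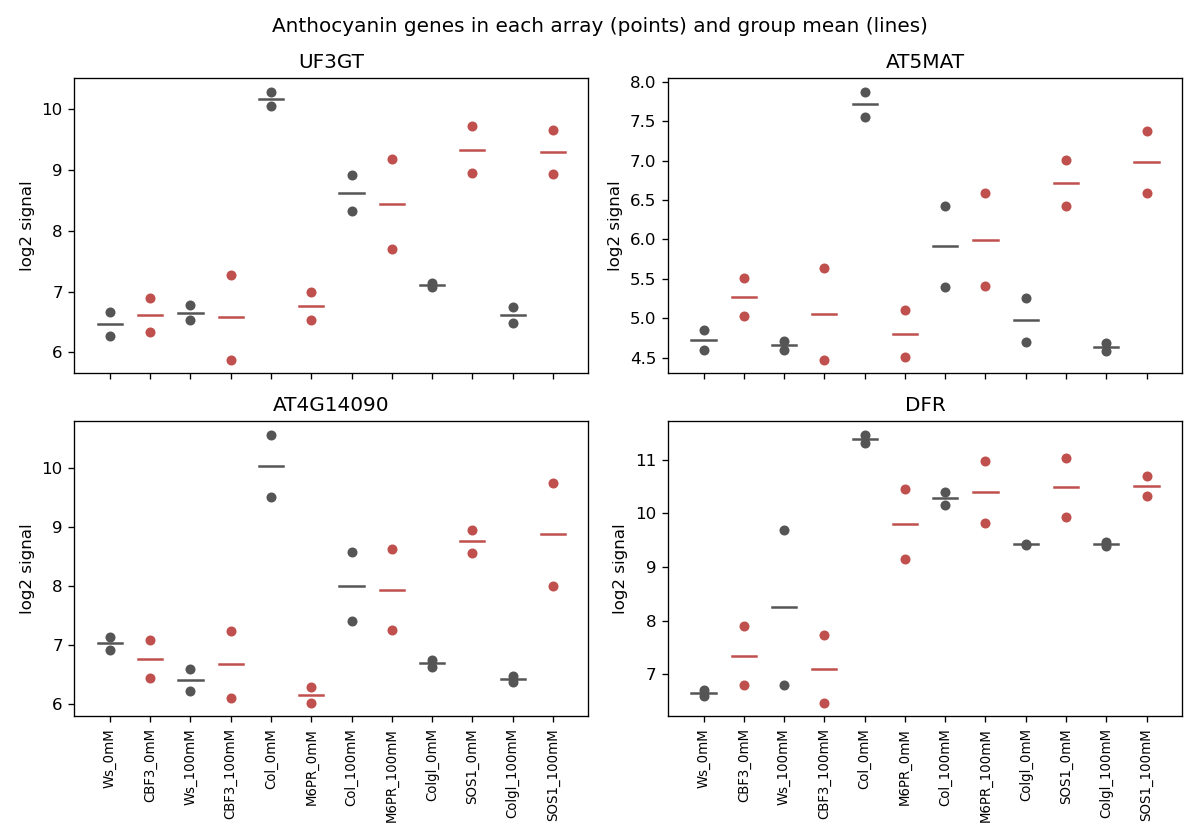
Log2 signal (y axis) of 4 flavonoid and anthocyanin genes in the 12 groups (x axis), with a point for each of the 2 arrays, a line at the group mean, wild types in grey and transgenic lines in red. UF3GT averaged 10.17 in Col_0mM and 6.76 in M6PR_0mM.

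In Ws, salt raised AT3G02480 by 7.21 ± 1.10 log2 units (SE, n = 2 arrays per group, adjusted p = 0.0025), XTH19 by 4.84 ± 0.61, EXLA1 by 4.45 ± 0.86 and the methyltransferase gene BSMT1 by 4.32 ± 0.92. In the CBF regulon LTI30 rose by 2.46, COR47 by 2.23 and COR15A by 1.55, 3 of 4 members over all probe sets and 4 when adjusted over the list alone (camera adjusted p = 1.8e-08, and adjusted p = 0.018 with an estimated correlation). STZ rose by 3.01, WRKY53 by 2.06 and CCS by 0.94. LEA4-5, the measured gene of the abscisic acid list, was at 3.50 ± 0.96 and did not pass (adjusted p = 0.0502). Its SD was 0.408 in Ws_0mM and 0.74 in Ws_100mM, but 3.12 in CBF3_100mM, which the pooled SE includes. Other rises were AT1G09500 (4.67), AT1G05340 (4.56), AT5G19120 (4.02) and AT3G15450 (3.78). The chloroplast genes rpl20 and rpl14 fell by 2.11 and 2.08 on the log2 scale and TRY by 1.36. Other falls were AT1G11700 (-2.91), AT1G78450 (-2.28), AT2G21560 (-2.27), AT2G15020 (-2.23), AT5G66740 (-2.02) and AT3G56160 (-2.01). Ws_100mM replicate 1 is one of the arrays with the low dap and 25S rRNA signals. The Ws_0mM arrays enter all these changes. Ws_0mM minus CBF3_0mM correlated with Col_0mM minus Colgl_0mM at r = 0.59 across probe sets. A state of the unsalted arrays was therefore not told apart from an effect of salt. limma called 1072 probe sets, 597 higher and 475 lower with salt (533 higher and 836 lower with centred arrays), and the median fold change of all probe sets was -0.03 as deposited and -0.13 with centred arrays. The Ws salt count was 123 without Ws_0mM replicate 1, 186 without Ws_0mM replicate 2, 275 without Ws_100mM replicate 1 and 1775 (884 higher and 891 lower) without Ws_100mM replicate 2. Other settings gave 656 with a separate fit per background, 2494 with array weights and 278 without the 2 arrays with a low dap spike-in.

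In CBF3, 2 probe sets passed, both higher with salt. They were BETA-VPE, a vacuolar processing enzyme gene, at 1.57 ± 0.18 log2 units (SE, n = 2 arrays per group, adjusted p = 0.0071), and 1 probe set without a gene in the table used here. LTI30 and COR15A had log2 fold changes of 0.02 and -0.06. The 4 CBF regulon genes averaged between 13.01 and 13.28 in both CBF3 groups, toward the upper end of the deposited values, and whether signals that high could rise further was not tested. At an unadjusted p below 0.05 there were 743 probe sets. The CBF3 salt count was 0 without CBF3_0mM replicate 1 and 83 without CBF3_100mM replicate 1. Other settings gave 0 with a separate fit per background, 1 with a trended and robust variance model and 4 with array weights.

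In Col, salt raised STZ by 4.90 ± 0.62 log2 units (SE, n = 2 arrays per group, adjusted p = 3e-04), LTI30 by 4.75 ± 0.44, AT3G02480 by 6.49 ± 1.10 and the defensin-like gene LCR69 by 4.59 ± 0.65. All 4 measured CBF regulon members rose, with COR15B at 1.78, COR47 at 1.06 and COR15A at 0.78 (camera adjusted p = 4.4e-05, and adjusted p = 0.1 with an estimated correlation). WRKY53 rose 8-fold (adjusted p = 0.00057), GRX480 by 2.09, CML38 by 3.62, the senescence-list factor gene WRKY6 by 1.41 and CCS by 1.35. Further rises were AT1G05340 (5.31), AT4G29780 (4.99), EXLA1 (4.98) and AT2G33850 (4.81). The defensin genes PDF1.2 and PDF1.2b fell by 3.79 and 3.58 on the log2 scale and JMT by 1.78. Of the anthocyanin genes, AT4G14090, AT5MAT and UF3GT fell by 2.04, 1.80 and 1.55, 3 of 4 members, without a call for the list (camera adjusted p = 0.07). The Col_0mM arrays, which stood apart from Colgl_0mM, enter these changes: without salt LTI30 averaged 5.85 in Col and 8.42 in Colgl, and AT4G14090 10.04 and 6.69. TRY was 4.28-fold lower, VTC4 of ascorbate synthesis fell by 0.95 and the Calvin cycle gene PRK fell by 0.43. Other falls were AT2G15020 (-4.42), AT2G27420 (-3.77), AT1G20070 (-3.36), AT1G67870 (-3.22), AT5G54130 (-3.03) and AT3G28270 (-2.93). limma called 4764 probe sets, 2302 higher and 2462 lower (1914 higher and 4119 lower with centred arrays), and the median fold change of all probe sets was -0.12 as deposited and -0.28 with centred arrays. Col_100mM replicate 1 has the low dap signal. The Col salt count was 1661 (831 higher and 830 lower) without Col_0mM replicate 1, 1902 without Col_0mM replicate 2 and 1409 without Col_100mM replicate 1. Other settings gave 8076 with array weights and 1731 without the 2 arrays with a low dap spike-in.

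In M6PR, salt raised ORA47 by 2.61 ± 0.42 log2 units (SE, n = 2 arrays per group, adjusted p = 0.011) and COR15A by 1.30 ± 0.18, 1 of 4 CBF regulon members over all probe sets and 2 when adjusted over the list alone (camera adjusted p = 0.00071, and adjusted p = 0.16 with an estimated correlation). No anthocyanin gene passed over all probe sets, while 3 of 4 did when adjusted over the list alone, AT4G14090 at 1.79 and UF3GT at 1.68 among them (camera adjusted p = 0.00071, and adjusted p = 0.16 with an estimated correlation). Other rises were AT1G04770 (3.22), AT2G37870 (2.51), AT1G60590 (2.09), AT5G05250 (1.96), AT1G68570 (1.94), AT3G53980 (1.38) and AT4G01460 (1.35). MCCA, of leucine breakdown, fell by 1.63 on the log2 scale, and other falls were AT3G23550 (-2.80), AT3G16530 (-2.71), AT5G54720 (-1.97), AT2G44670 (-1.74), AT5G25440 (-1.73), AT5G27920 (-1.60) and AT5G58090 (-1.49). limma called 123 probe sets, 37 higher and 86 lower (34 higher and 149 lower with centred arrays), and fold changes correlated with those of salt in Col at r = 0.03 across probe sets. Shared with salt in Col were 17 calls upward and 24 downward, against 3.74 and 9.31 for independent lists, and 12 were opposite. The M6PR salt count was 11 without M6PR_0mM replicate 1, 20 without M6PR_0mM replicate 2, 26 without M6PR_100mM replicate 1 and 375 without M6PR_100mM replicate 2.

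In Colgl, 30 probe sets passed, 17 higher and 13 lower with salt. The iron-related factor gene BHLH101 rose by 0.90 ± 0.16 log2 units (SE, n = 2 arrays per group, adjusted p = 0.037), the chloroplast genes rps4 and psaB by 1.93 and 0.92, and AT5G05250 (2.54), IQD22 (1.19), AT4G18250 (0.89) and AT5G45060 (0.82) were also higher. SIR, the sulfite reductase gene, fell by 0.92 on the log2 scale and SDH2-2, for a succinate dehydrogenase subunit, by 0.68. Other falls were AT2G36885 (-1.45), AT1G68650 (-1.43), AT3G05730 (-1.19) and AT5G51010 (-1.12). None of the 4 CBF regulon genes passed, with LTI30 at 0.32 ± 0.44. The Colgl salt count was 0 without Colgl_0mM replicate 1, 5 (2 higher and 3 lower) without Colgl_0mM replicate 2, 0 without Colgl_100mM replicate 1 and 0 without Colgl_100mM replicate 2. Other settings gave 1519 with array weights.

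In SOS1, limma called 0 probe sets for salt, with 1694 at an unadjusted p below 0.05. The smallest p-values were those of AT3G23170, AT1G33760 and AT2G36885, at -2.03 ± 0.33, -1.56 ± 0.28 and -0.95 ± 0.18 log2 units (SE, n = 2 arrays per group). The CBF regulon was called as a list (camera adjusted p = 0.0027, and adjusted p = 0.31 with an estimated correlation), with LTI30 at 1.92 ± 0.44 and 2 members passing when adjusted over the list alone. The SOS1 salt count was 18 without SOS1_0mM replicate 1, 3787 without SOS1_0mM replicate 2, 255 without SOS1_100mM replicate 1 and 1 without SOS1_100mM replicate 2. Other settings gave 1 with a separate fit per background.

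Averaged over the 3 wild types, salt raised AT2G16660 (1.57), AT3G53980 (1.82), AT3G62550 (1.41) and AT1G32920 (2.43) and lowered AT3G05730 (-1.33), as log2 fold changes; these 5 had the smallest p-values. limma called 4593 probe sets, 2328 higher and 2265 lower (1751 higher and 4657 lower with centred arrays), and the median fold change of all probe sets was -0.06 as deposited and -0.18 with centred arrays. Fold changes of salt correlated across probe sets with r = 0.73 between Ws and Col, 0.07 between Ws and Colgl and 0.14 between Col and Colgl. Ws and Col shared 379 calls upward and 348 downward, against 60.4 and 51.4 for independent lists. The Ws_0mM and Col_0mM arrays enter these changes, so a state of the unsalted arrays was not told apart from salt. The average salt count was 3048 without Ws_100mM replicate 1 and 3019 (1500 higher and 1519 lower) without Col_100mM replicate 1. Other settings gave 8709 (4150 higher and 4559 lower) with array weights and 2257 without the 2 arrays with a low dap spike-in.

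The salt response of CBF3 differed from that of Ws in 16 probe sets, 4 with a higher and 12 with a lower response in CBF3 (15 higher and 18 lower after quantile normalization, 7 higher and 10 lower with centred arrays), and the median fold change of all probe sets was 0.04 as deposited and 0.15 with centred arrays. AT3G62550 and AT4G19430 had the smallest p-values, at -2.62 ± 0.28 and -1.74 ± 0.19 log2 units (SE), followed by AT1G78450 (2.34), AT4G26950 (1.60) and AT2G16660 (-1.96). COR15A was lower by 1.61, and the CBF regulon was called as a list (camera adjusted p = 2.1e-08, and adjusted p = 0.019 with an estimated correlation). All 4 genes were already between 13.01 and 13.28 in CBF3 without salt, so a ceiling of the signal was not separated from a lower response. Ws_0mM enters the interaction too, and a state of those arrays was not told apart from a difference in salt response. The CBF3 interaction count was 5 without Ws_0mM replicate 1, 5 without Ws_0mM replicate 2, 3 without CBF3_0mM replicate 1, 41 without CBF3_0mM replicate 2, 474 without Ws_100mM replicate 2 and 7 without CBF3_100mM replicate 1. Other settings gave 9 with a separate fit per background, 33 after quantile normalization and 109 with array weights.

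The salt response of M6PR differed from that of Col in 1382 probe sets, 742 upward and 640 downward, and the median fold change of all probe sets was 0.10 as deposited and 0.26 with centred arrays. The defence factor gene WRKY22 was at -4.05 ± 0.46 log2 units (SE, adjusted p = 0.0015), and AT3G15310 (1.66), AT5G58090 (-2.35), AT2G16660 (-2.34) and AT1G32920 (-3.99) complete the 5 with the smallest p-values. Of the 4 anthocyanin genes 3 passed upward, AT4G14090 at 3.83 (camera adjusted p = 0.0022, and adjusted p = 0.37 with an estimated correlation), and STZ was at -4.20. Col_0mM, which stood apart from Colgl_0mM, enters this difference: AT4G14090 averaged 10.04 in Col_0mM, 6.16 in M6PR_0mM and 6.69 in Colgl_0mM. The M6PR interaction count was 264 (117 higher and 147 lower) without Col_0mM replicate 1, 330 without Col_0mM replicate 2, 627 without M6PR_0mM replicate 1, 208 (96 higher and 112 lower) without M6PR_0mM replicate 2, 383 (158 higher and 225 lower) without Col_100mM replicate 1, 150 without M6PR_100mM replicate 1 and 3860 without M6PR_100mM replicate 2. Other settings gave 1086 (437 higher and 649 lower) with a separate fit per background, 2358 (1171 higher and 1187 lower) with array weights and 367 (158 higher and 209 lower) without the 2 arrays with a low dap spike-in.

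For SOS1 and Colgl, limma called 0 probe sets in the interaction, with 672 at an unadjusted p below 0.05. The smallest p-values were those of AT4G18250 (-1.05), BHLH101 (-1.04) and UGT71B6 (-1.17), with adjusted p = 0.93. The CBF regulon list was called (camera adjusted p = 0.029, and adjusted p = 0.49 with an estimated correlation), with LTI30 at 1.60 ± 0.62 log2 units. The SOS1 interaction count was 1 without Colgl_0mM replicate 2, 1 without SOS1_0mM replicate 1, 661 without SOS1_0mM replicate 2 and 33 without SOS1_100mM replicate 1. Other settings gave 5 with a separate fit per background and 1 with a trended and robust variance model.

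Without salt, the effect of CBF3 (line minus wild type) exceeded that of M6PR for LTI30 by 6.54 ± 0.62 log2 units (SE) and for COR15A by 3.52 ± 0.26, with AT2G24560 (4.42), AT3G15310 (1.88) and AT4G01140 (2.82) also among the 5 smallest p-values. Against SOS1 the difference was 9.11 ± 0.62 for LTI30 and 3.11 ± 0.26 for COR15A, with AT2G24560 (4.12), AT3G62550 (4.25) and AT3G53990 (3.58). Between M6PR and SOS1 the smallest p-values were those of AT3G15310 (-2.22), AT4G01460 (-3.21), AT5G62865 (3.82), AT2G15880 (3.35) and AT1G60590 (-6.23). Col_0mM enters every difference with M6PR. It stood apart from Colgl_0mM in 3209 probe sets, against 8 for M6PR_0mM. The effects differed in 268 probe sets between CBF3 and M6PR (173 higher and 95 lower, 164 higher and 146 lower after quantile normalization, 149 higher and 138 lower with centred arrays), 1234 between CBF3 and SOS1 (692 higher and 542 lower) and 2582 between M6PR and SOS1. Fold changes of the lines without salt correlated across probe sets with r = 0.59 for CBF3 and M6PR, r = -0.07 for CBF3 and SOS1 and r = -0.5 for M6PR and SOS1. For CBF3 and M6PR there were 1710 (832 higher and 878 lower) with array weights. Counts for CBF3 and M6PR were 125 without Ws_0mM replicate 1, 134 without Ws_0mM replicate 2, 152 without CBF3_0mM replicate 1, 119 without Col_0mM replicate 1, 124 without Col_0mM replicate 2, 146 without M6PR_0mM replicate 1 and 139 without M6PR_0mM replicate 2; for CBF3 and SOS1, 543 without Ws_0mM replicate 1, 612 without Ws_0mM replicate 2, 524 without CBF3_0mM replicate 1, 517 without Colgl_0mM replicate 1, 553 without Colgl_0mM replicate 2, 1002 (423 higher and 579 lower) without SOS1_0mM replicate 1 and 3168 without SOS1_0mM replicate 2; for M6PR and SOS1, 1651 without Col_0mM replicate 1, 1668 without M6PR_0mM replicate 2, 1695 without Colgl_0mM replicate 1, 1638 without Colgl_0mM replicate 2 and 4950 without SOS1_0mM replicate 2.

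The size of change, the root mean square log2 difference estimated from independent array pairs so that array noise averages out, was 0.541 for CBF3, 0.603 for M6PR and 0.259 for SOS1 without salt. With salt it was 0.374, 0.365 and 0.345. The M6PR value without salt is a difference from Col_0mM, which stood apart from Colgl_0mM in 3209 probe sets, against 8 for M6PR_0mM. So it does not give the size of the transgene effect alone. The CBF3 and SOS1 values are likewise differences from Ws and Colgl arrays, whose state was not told apart from a transgene effect. For salt itself the size of change was 0.456 in Ws, 0.68 in Col, 0.253 in Colgl and 0.215 in M6PR. The M6PR value joins 0.293 from arrays paired by number and 0.081 from the crossed pairing. Pairings are joined by averaging their mean products before the root, so the result is not the average of the printed values. For salt in SOS1 the size of change was below 0 in both pairings (-0.219 and -0.323, joined -0.276). For salt in CBF3 the pairings gave opposite signs (0.148 and -0.252, joined -0.144). With 2 arrays per group these values have no test. Of the other tested lists, none was called in the 15 comparisons: the lowest adjusted p was 0.2 for mannose, ascorbate and polyols (4 measured genes), 0.24 for antioxidants (3), 0.07 for photosynthesis (4) and 0.07 for gibberellin (3). The genes of the single-member lists for flowering (FD), roots (EXPA7) and guard cells (FMA) passed in none of the 12 two-group comparisons, nor did DELTA-OAT and AT5G38710 of the proline and sugar list.

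**Figure D4:**
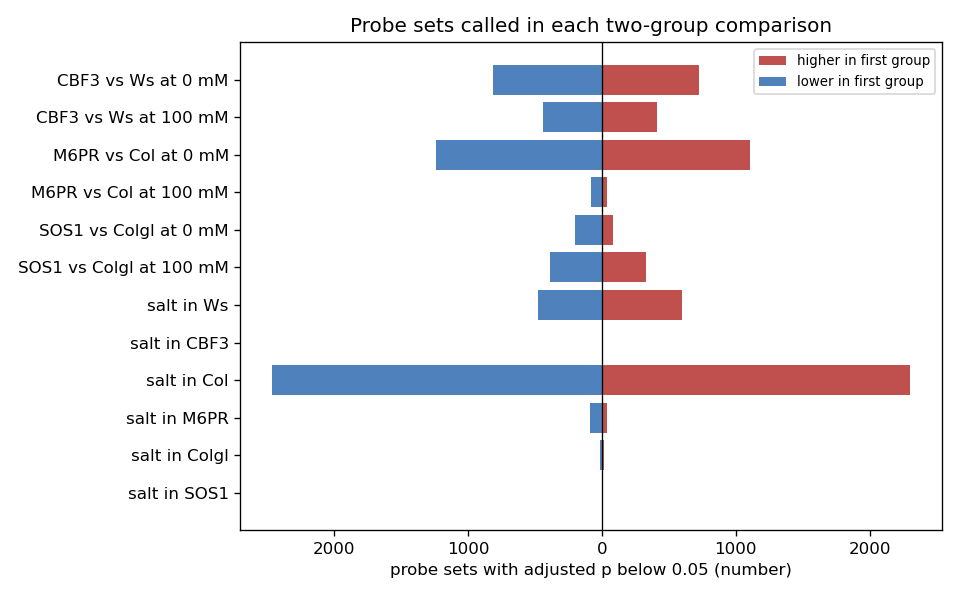
Number of probe sets with adjusted p below 0.05 (x axis) in each of the 12 two-group comparisons (y axis), with red bars for those higher and blue bars for those lower in the first-named group or with salt. Salt in Col has the longest bars (2302 higher, 2462 lower) and salt in SOS1 has 0.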

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

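The tests of explanations in this part were chosen after the results were seen, while the 5 differences themselves were planned. Effects differed between groups in each of them. The salt response differed between CBF3 and Ws in 16 probe sets and between M6PR and Col in 1382. Without salt, line effects differed in 268 probe sets between CBF3 and M6PR, 1234 between CBF3 and SOS1 and 2582 between M6PR and SOS1.

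M6PR against Col gave 2346 calls without salt (944 to 1220 with single arrays left out) and 120 with it (10 to 3720, the lowest without M6PR_100mM replicate 1 and the highest without its replicate 2), but 4618 and 5304 at an unadjusted p below 0.05. Against the transgene alone as the cause, M6PR_0mM differed from Colgl_0mM, the other Columbia wild type, in 8 probe sets, while Col_0mM differed from Colgl_0mM in 3209. Against RNA degradation in Col_0mM, the actin 3' minus 5' signal of its 2 arrays (2.48 and 2.53) lay within the range of the M6PR_0mM and Colgl_0mM arrays (2.42 to 2.86). Col_0mM minus Colgl_0mM correlated with Ws_0mM minus CBF3_0mM, which shares no array with it, at r = 0.59 across probe sets. The effects of CBF3 and M6PR without salt had already correlated at r = 0.59. With M6PR_0mM so near to Colgl_0mM, the correlation largely restates that value and is no separate test. A state shared by the Col and Ws arrays without salt is a candidate explanation. A state shared by M6PR_0mM and the Colgl arrays is another, since Col_100mM also differed from Colgl_100mM, in 2379 probe sets. The values do not tell one from the other. What either state is (sampling, growth or handling) was not tested. Effects of the transgenes that add to it stay open, as do effects with salt, where M6PR_100mM differed from Colgl_100mM in 899 probe sets.

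Salt called 1072 probe sets in Ws and 4764 in Col but 30 in Colgl (123 to 1775, 1409 to 3892 and 0 to 5 with single arrays left out). The 2 arrays with a low dap spike-in are not the whole cause: from replicate 2 of the 100 mM groups alone, salt in Ws and salt in Col correlated at r = 0.65 across all probe sets. That test replaced an earlier one on called probe sets, which was set aside because replicate 2 had helped to pick them. Col_0mM differed from Colgl_0mM in 3209 probe sets and Col_100mM from Colgl_100mM in 2379. A state of the unsalted Ws and Col arrays and a weaker salt response in Colgl cannot be told apart, since both enter the same difference. The low count does not show that Colgl lacks a salt response. It was 1519 with array weights and 30 with a separate fit per background, and the size of change was 0.253. A biological difference between the wild types stays open and untested.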

How the results depend on the processing

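The fit without the 2 arrays with a low dap spike-in and the crossed pairing were chosen after seeing the data. No named gene that passed changed direction under any alternative. Leaving out cross-hybridizing probe sets kept all 19 counts within 1.5 times, and the mean of each called list or family kept its sign under both scalings. Counts within 1.5 times the reported one are not listed; the cause of the changes below was not tested. Without the dimmest 40% of probe sets the count was 58 for M6PR vs Col at 100 mM. A separate fit per background gave 656 for salt in Ws, 0 for salt in CBF3, 9 for CBF3 by salt interaction, 49 for M6PR vs Col at 100 mM, 51 for SOS1 vs Colgl at 0 mM, 246 for SOS1 vs Colgl at 100 mM, 1 for salt in SOS1 and 5 for SOS1 by salt interaction. Quantile normalization gave 33 for CBF3 by salt interaction, median centring 489 for SOS1 vs Colgl at 0 mM, and the trended and robust model 1 for salt in CBF3 and 1 for SOS1 by salt interaction. Array weights gave 3780 for CBF3 vs Ws at 0 mM, 2494 for salt in Ws, 4 for salt in CBF3, 109 for CBF3 by salt interaction, 5332 for M6PR vs Col at 0 mM, 37 for M6PR vs Col at 100 mM, 8076 for salt in Col, 2358 for M6PR by salt interaction, 8 for SOS1 vs Colgl at 0 mM, 1145 for SOS1 vs Colgl at 100 mM, 1519 for salt in Colgl, 8709 for salt in the 3 wild types and 1710 for CBF3 effect vs M6PR effect at 0 mM. Without the 2 low-dap arrays counts were 318 for CBF3 vs Ws at 100 mM, 278 for salt in Ws, 42 for M6PR vs Col at 100 mM, 1731 for salt in Col, 367 for M6PR by salt interaction and 2257 for salt in the 3 wild types. Calls of named genes lost were 74 with a separate fit per background, 40 without the low-dap arrays, 26 with array weights, 7 with centring, 5 with quantile normalization, 2 with the trended model, 1 without dim probe sets and 338 over all fits without 1 array (706 kept). Leaving out single arrays, the remaining one assumed to vary like other groups, gave 463 to 1510 for CBF3 vs Ws at 0 mM, 123 to 1775 for salt in Ws, 3 to 474 for CBF3 by salt interaction, 3019 to 5080 for salt in the 3 wild types, 119 to 238 for CBF3 effect vs M6PR effect at 0 mM, 517 to 3168 for CBF3 effect vs SOS1 effect at 0 mM, 0 to 83 for salt in CBF3, 278 to 1367 for CBF3 vs Ws at 100 mM, 944 to 1220 for M6PR vs Col at 0 mM, 1409 to 3892 for salt in Col, 150 to 3860 for M6PR by salt interaction, 1638 to 4950 for M6PR effect vs SOS1 effect at 0 mM, 11 to 375 for salt in M6PR, 10 to 3720 for M6PR vs Col at 100 mM, 16 to 4439 for SOS1 vs Colgl at 0 mM, 0 to 5 for salt in Colgl, 0 to 661 for SOS1 by salt interaction, 1 to 3787 for salt in SOS1, 88 to 1483 for SOS1 vs Colgl at 100 mM. Size of change without dim probe sets was 0.666 for CBF3 vs Ws at 0 mM, 0.454 for CBF3 vs Ws at 100 mM, 0.566 for salt in Ws, 0.759 for M6PR vs Col at 0 mM, 0.404 for M6PR vs Col at 100 mM, 0.819 for salt in Col, 0.368 for SOS1 vs Colgl at 0 mM, 0.417 for SOS1 vs Colgl at 100 mM and 0.311 for salt in Colgl; with centred arrays it was 0.461 for salt in Ws, 0.701 for salt in Col and 0.343 for SOS1 vs Colgl at 100 mM. Sizes of change are listed where they moved by more than a spread taken from the 2 pairings. Within that spread, centred arrays gave 0.392 for M6PR vs Col at 100 mM, 0.241 for SOS1 vs Colgl at 0 mM and 0.197 for salt in M6PR, among others. The scale alternative was not run, since values were on a log scale. The DREB1A and SOS1 probe sets could not be picked out by gene, so no value is given for them under any setting.

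Replicate numbers do not tie arrays of different groups to a shared source in the labels. Deviations of arrays with the same number correlated above 0.1 in 6 of 12 comparisons and below -0.1 in 2. The replicate block gave 7 for CBF3 by salt interaction, 71 for M6PR vs Col at 100 mM and 174 for SOS1 vs Colgl at 0 mM, and other counts stayed within 1.5 times, with 32 calls of named genes lost. With the block the CBF regulon was called in 10 of 15 comparisons, against 9. A crossed pairing in the 2 comparisons below -0.1 gave 1017 for M6PR vs Col at 100 mM and 19 for salt in Colgl, with 8 calls of named genes lost.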

Other observations

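The tests of sample background in this part were chosen after the result was seen. The splits of the samples were set before. Counts of family genes are of the genes matched here, which can be a small part of a family. Of 12 glutathione S-transferase genes, 3 were lower in CBF3 than in Ws without salt, GSTU23 (-1.60), GSTF4 and GSTU18 (-0.76) on the log2 scale (mean of the family -0.44, adjusted p = 0.0074, and adjusted p = 0.042 with an estimated correlation). In M6PR against Col without salt the mean of the family was -0.20 (adjusted p = 0.62, and adjusted p = 0.8 with an estimated correlation), with salt in Colgl -0.20 (adjusted p = 0.028, and adjusted p = 0.28 with an estimated correlation), and the salt response of CBF3 differed from that of Ws by 0.35 (adjusted p = 0.047, and adjusted p = 0.17 with an estimated correlation).

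Chloroplast-encoded genes, 69 of which were measured, had a mean log2 fold change with salt of -1.41 in Ws, with 5 genes lower (adjusted p = 4.8e-18, and adjusted p = 0.24 with an estimated correlation), and 0.94 in Colgl, with 2 higher (adjusted p = 2.7e-20, and adjusted p = 0.5 with an estimated correlation). In Col the mean was -0.66 (adjusted p = 0.23, and adjusted p = 0.85 with an estimated correlation), in CBF3 -0.22 (adjusted p = 0.00048, and adjusted p = 0.89 with an estimated correlation) and in M6PR -0.40 (adjusted p = 0.00053, and adjusted p = 0.66 with an estimated correlation). Between lines it was 1.17 for CBF3 against Ws with salt (adjusted p = 2.8e-09, and adjusted p = 0.82 with an estimated correlation) and 0.91 for SOS1 against Colgl without salt (adjusted p = 3.6e-09, and adjusted p = 0.78 with an estimated correlation). For M6PR against Col without salt it was 0.26 (adjusted p = 0.019, and adjusted p = 0.8 with an estimated correlation). The salt response differed between CBF3 and Ws by a mean of 1.19 (adjusted p = 1.3e-08, and adjusted p = 0.55 with an estimated correlation) and between SOS1 and Colgl by -0.88 (adjusted p = 8.9e-14, and adjusted p = 0.65 with an estimated correlation), while salt in SOS1 gave 0.07 (adjusted p = 0.93, and adjusted p = 0.98 with an estimated correlation). Several of these means share arrays and are not separate results. Salt in Colgl, SOS1 against Colgl without salt and the SOS1 interaction all include Colgl_0mM. Salt in Ws, CBF3 against Ws with salt and the CBF3 interaction all include Ws_100mM. The difference between Ws and Colgl was not tested. Replicate 1 of Ws_100mM and of Col_100mM had the low dap signals (6.73 and 7.1), low 25S rRNA signals (4.98 and 4.52) and a 3' minus 5' actin signal of 3.84 in both, against at most 3.15 in the other arrays.

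Of 10 genes for xyloglucan endotransglucosylase/hydrolases, which remodel the cell wall, salt in Ws raised XTH19 (4.84) and XTH18 (2.97), with a family mean of 1.32 (adjusted p = 0.0011, and adjusted p = 0.18 with an estimated correlation). The mean was 0.96 (adjusted p = 0.039, and adjusted p = 0.37 with an estimated correlation) for M6PR against Col without salt, with 3 genes higher and 1 lower, and -1.24 (adjusted p = 0.0039, and adjusted p = 0.17 with an estimated correlation) for the CBF3 interaction. The 8 calmodulin-like genes had means of 0.62 (adjusted p = 0.037, and adjusted p = 0.24 with an estimated correlation) for salt in Ws, 0.97 (adjusted p = 0.034, and adjusted p = 0.43 with an estimated correlation) for salt in Col, 0.91 (adjusted p = 0.039, and adjusted p = 0.4 with an estimated correlation) for M6PR against Col without salt and -1.13 (adjusted p = 0.022, and adjusted p = 0.56 with an estimated correlation) for the M6PR interaction. The 7 WRKY factors had means of 0.54 (adjusted p = 0.045, and adjusted p = 0.24 with an estimated correlation) for salt in Ws and 0.74 (adjusted p = 0.039, and adjusted p = 0.37 with an estimated correlation) for M6PR against Col without salt. For the 51 UDP-glycosyltransferases the means were 0.20 (adjusted p = 0.024, and adjusted p = 0.82 with an estimated correlation) in CBF3 against Ws with salt, 0.31 (adjusted p = 0.00033, and adjusted p = 0.78 with an estimated correlation) and 0.33 (adjusted p = 0.036, and adjusted p = 0.79 with an estimated correlation) in SOS1 against Colgl without and with salt, 0.26 (adjusted p = 0.0048, and adjusted p = 0.66 with an estimated correlation) for salt in M6PR and 0.57 (adjusted p = 0.0093, and adjusted p = 0.71 with an estimated correlation) for the M6PR interaction, where 8 genes passed upward and 1 downward. The 11 autophagy genes had means of 0.34 (adjusted p = 0.037, and adjusted p = 0.38 with an estimated correlation) for salt in Ws, 0.18 (adjusted p = 0.039, and adjusted p = 0.51 with an estimated correlation) in Colgl and -0.30 (adjusted p = 0.044, and adjusted p = 0.66 with an estimated correlation) in M6PR, and the 8 histone genes 0.75 (adjusted p = 0.013, and adjusted p = 0.48 with an estimated correlation) in Col and 0.32 (adjusted p = 0.044, and adjusted p = 0.66 with an estimated correlation) in M6PR. Called once each were bZIP factors for salt in Ws, at 0.26 (adjusted p = 0.037, and adjusted p = 0.18 with an estimated correlation), trichome birefringence-like genes for CBF3 against Ws with salt, at -0.33 (adjusted p = 0.015, and adjusted p = 0.073 with an estimated correlation), and SWEET sugar transporters for the M6PR interaction, at 0.61 (adjusted p = 0.022, and adjusted p = 0.56 with an estimated correlation). Expansins, MADS box genes, auxin-responsive genes, beta-glucosidases, serine carboxypeptidase-like genes and RALF-like peptides were called in none of the 15 comparisons. The means for salt in Ws and for the CBF3 interaction share the Ws arrays and are not separate results. A state of Ws_0mM was not told apart from salt in them. Col_0mM enters the means for M6PR against Col without salt, for salt in Col and for the M6PR interaction. It stood apart from Colgl_0mM in 3209 probe sets, against 8 for M6PR_0mM.

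The description texts put the CBF3 arrays in Columbia and the M6PR arrays in Ws, against their titles. On 39 probe sets that separated the Ws arrays from all Col and Colgl arrays by over 2 log2 units, 100% were nearer to the Ws level in every CBF3 array and 0% in every M6PR array. Both values are against the backgrounds in the description texts, and the titles were used.

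The average salt effect over wild types (4593 calls) was set against 100 splits that exchange salt labels within a background, the real one included. 1 split, the real one, gave as many, and the highest other gave 3702. That one was among 5 that exchange labels in Colgl alone, and the remaining 94 gave at most 31. The count therefore rests on the structure of the Ws and Col arrays. A split that mixes salt levels within a group adds their difference to the residual spread, so few calls are left. The splits show that arrays of a group resemble each other. They cannot tell an effect of salt from another difference shared by both arrays of a group.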
